A study of Mus musculus with 2 samples.

How the data were processed

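The series holds 2 sequencing libraries from mouse CD8+ T cells: 1 chromatin immunoprecipitation (ChIP-seq) with an antibody against histone H3 β-hydroxybutyrylated at lysine 9 (H3K9bhb), and 1 input DNA library. Per the labels' protocols, splenocytes from OT-I mice (transgenic for a T cell receptor that recognises an ovalbumin peptide) were activated for 3 days with the peptide at 200 ng/ml and interleukin-2 at 10 ng/ml. They were then kept in interleukin-15 at 10 ng/ml for 4 days, which turns them into memory-like cells, and were treated with β-hydroxybutyrate for 3 days. The immunoprecipitation used 4 µg of antibody and a commercial high-sensitivity kit. Libraries were sequenced as paired-end reads of 150 bp, and the labels give 70 M reads per experiment.

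The values used were the peak list of the ChIP library. Per the submitters' processing notes, FastQC 0.11.8, Trimmomatic 0.39, Bowtie2 2.3.5 and MACS2 2.1.2 were used with genome build mm10. The settings of the peak caller, the use of the input as its control, the removal of duplicates or of blacklisted regions and the handling of reads that map to many places are not given in the sources used here. The list is written like a MACS2 summit file: each row is a position of 1 bp with a peak name and a value. The deposited values are the authors' −log10 p or q values at each summit; which of the 2 they are is not given in the sources used here. They are called scores from here on. Peak widths, fold enrichments and read counts were not analysed here, so the depth behind a single peak is unknown. The score also depends on local read depth, so it was used only within this list, to rank and filter peaks and to compare peaks on X with those on autosomes.

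The list holds 2315 summits of 2204 peaks, and each peak was represented by its highest-scoring summit. Positions were set against a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 denotes, with 21900 protein-coding genes. This table gives the start and end of each gene but not its strand, its exons or the genome sequence. The design, the gene lists and the rule for named genes were chosen before the data were examined. The design named promoters, untranslated regions, exons and introns. These were replaced by 3 classes: within 2 kb of either end of a protein-coding gene, inside a gene but farther from its ends, and outside genes. A gene end is therefore either its transcription start or its transcript end. A gene was counted as having a peak when a summit lay inside it or within 5 kb on either side, in place of 5 kb upstream of the start. The planned measures of repeat content and GC content were not run for the same reason. Peak width was not measured because each row of the list is a position of 1 bp.

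Observed shares were set against 1000 random placements of the same number of summits, each on its own chromosome between the first and last annotated gene. Peaks per Mb were counted over that same annotated span. Assembly gaps, which the design left out of both, were not removed. Gene lists (18 lists, 313 distinct genes, all matched to the table) covered T cell states, metabolism, signalling, other blood cells and reference genes. The number of members with a peak was set against 10000 random lists of protein-coding genes matched on gene length in 10 bins. With 1 ChIP library there is no replicate, so no p-value is given; the random draws describe this peak list and not the spread between cultures. Intervals are exact (Clopper-Pearson, or exact Poisson for counts per Mb) at 95% and cover counting error only. For the ketone body and effector lists, which held no peak, the share allowed is also given as 3 counts of the total. The genes named are Foxo1, Ppargc1a and Pck1, taken from what is known of the study and not from its labels; list members with a peak, up to 6 per list by score; the 20 highest-scoring peaks; and the 10 genes with the most peaks, with ties. Some list members with a peak are counted but not reported here by name. Genes chosen otherwise are said to have been chosen after their values were seen.

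The counting functions were tested on simulated summits over the 21900 genes. All of 200 seeded genes (100%) were found, a share near gene ends of 15.0% was returned as put in, and a list of 20 genes with 10 seeded members had as many members with a peak as none (0%) of its random lists. The seeded summits were placed inside the counting windows, and both shares came from the same function. These outcomes were therefore largely fixed by construction: they check the code and do not bear on the deposited peaks. Of 400 random lists used as a calibration, 2.25% fell in the upper 5% tail. Alternatives covered the window around gene ends, the flank around genes, all annotated genes, stricter score thresholds, merging of peaks within 10 kb, placement over the whole genome and unmatched random lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.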

Results

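H3K9bhb is a histone mark formed from the ketone body β-hydroxybutyrate, and the series profiled where it lies in the genome of interleukin-15-induced CD8+ memory T cells treated with that metabolite. The data consist of 1 ChIP library and 1 input library, each given as 70 M reads, and the peak list of the ChIP library. No untreated culture and no second ChIP library were analysed here, so a peak marks a place called in treated cells and not a response to the treatment. A call does not by itself show the mark, since 9 peaks lay on the mitochondrial genome, which carries no histones. The list held 2204 peaks with a median score (−log10 p or q) of 5.04, quartiles of 3.33 and 6.78 and a range from 2.01 to 1167.46. Several summits were called in 94 peaks. Scores were coarse: the 10 commonest values were shared by 764 peaks (34.7%).

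The H3K9bhb peaks lay at the ends of genes. Of the 2204 summits, 1817 (82.4%, 95% interval 80.8 to 84.0) were within 2 kb of an end of a protein-coding gene, 12.96-fold more than the 6.36% ± 0.51 (SD over 1000 random placements) found for random positions. A further 283 summits (12.8%) were inside genes and farther from their ends, against 37.3% ± 1.04 for random placement. Another 104 summits (4.72%) were outside genes and over 2 kb from an end, against 56.3% ± 1.05. All 1000 placements gave lower values at gene ends (highest 8.39%) and higher values in the other classes (lowest 33.8% inside and 52.8% outside genes).

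Most summits at gene ends were on the transcribed side. Of the 1817, 1529 (84.1%) were inside the gene, with a median position 206 bp inside the annotated end and quartiles of 73 and 420 bp. The stretch from 0 to 500 bp inside a gene end alone held 1162 summits (52.7% of all peaks). The end with the lower coordinate was the nearer in 898 of the 1817 (49.4%, 95% interval 47.1 to 51.7). Without the strand of each gene, this share does not tell transcription starts from transcript ends. For 283 of them (15.6%), ends of several genes lay within 2 kb.

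**Figure D1:**
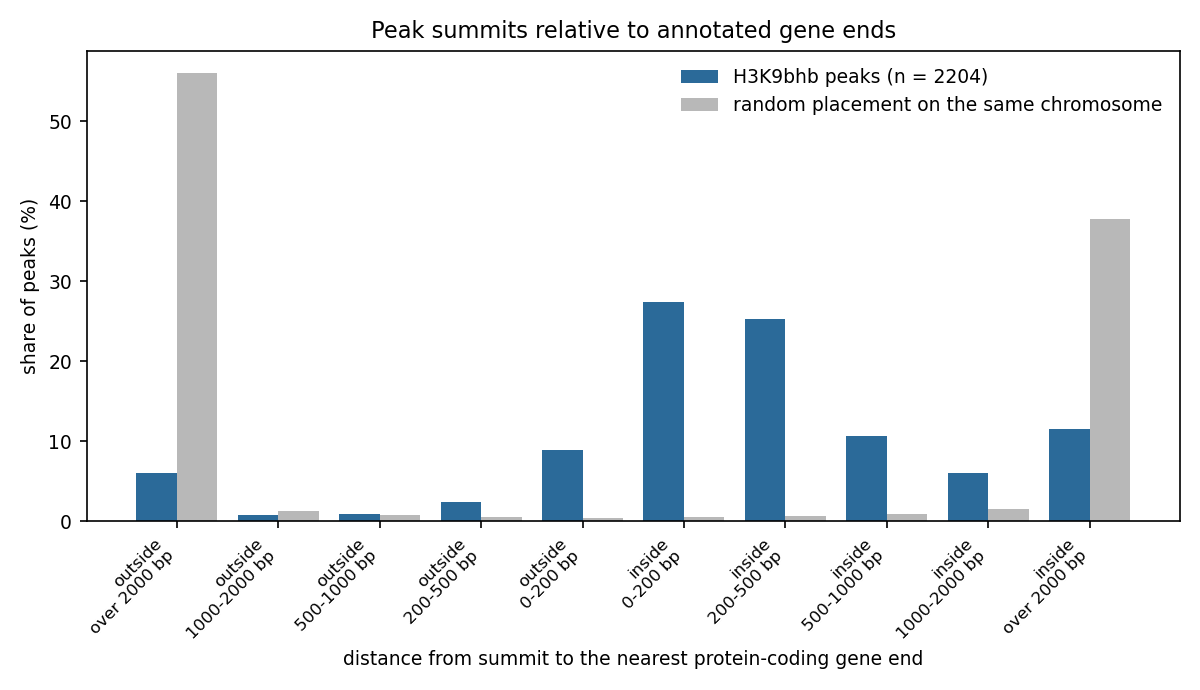
Share of peak summits (%, vertical axis) by distance to the nearest protein-coding gene end (horizontal axis, bp, outside or inside the gene), for the 2204 H3K9bhb peaks (blue) and for random placement on the same chromosomes (grey). The bins from 0 to 200 bp and from 200 to 500 bp inside a gene hold 27.5% and 25.3% of the peaks, against 0.524% and 0.597% of random positions. A peak counts as inside when it lies in the gene with the nearest end, a random position when it lies in any gene.

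The next question was whether Foxo1, Ppargc1a and Pck1, taken from what is known of the study and not from its labels, had a called peak. Foxo1 and Ppargc1a had peaks and no peak was called at Pck1. Foxo1 (chromosome 3, 52268337 to 52350109), a transcription factor of naive and memory T cells, had a summit 316 bp outside its lower-coordinate end, at 52268021, and another 1550 bp inside it, at 52269887. Both scored 3.17, and 80.4% of all peaks scored as high or higher. Ppargc1a (chromosome 5, 51454249 to 52115853), which encodes the coactivator PGC-1α of mitochondrial biogenesis, had 1 summit at 52113663, inside the gene and 2190 bp from its higher-coordinate end. It scored 4.54, and 56.6% of peaks scored as high or higher. The annotated span of Ppargc1a was 661605 bp, and no summit lay within 2 kb of either end. Chromosome 5 carried 1.09 peaks per Mb, so a region this long has much room for a summit by position alone. Of all protein-coding genes, 11.4% had a peak inside them or within 5 kb, so a gene without one is the common case. These genes were not set against random placement one by one. The gene table does not give which end is the start or where promoters lie, so this peak cannot be assigned to a promoter. Pck1 (chromosome 2, 173153073 to 173159274), which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was 117.4 kb from the closest summit, at 173276636, which lay 95 bp from an end of Pmepa1.

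**Figure D2:**
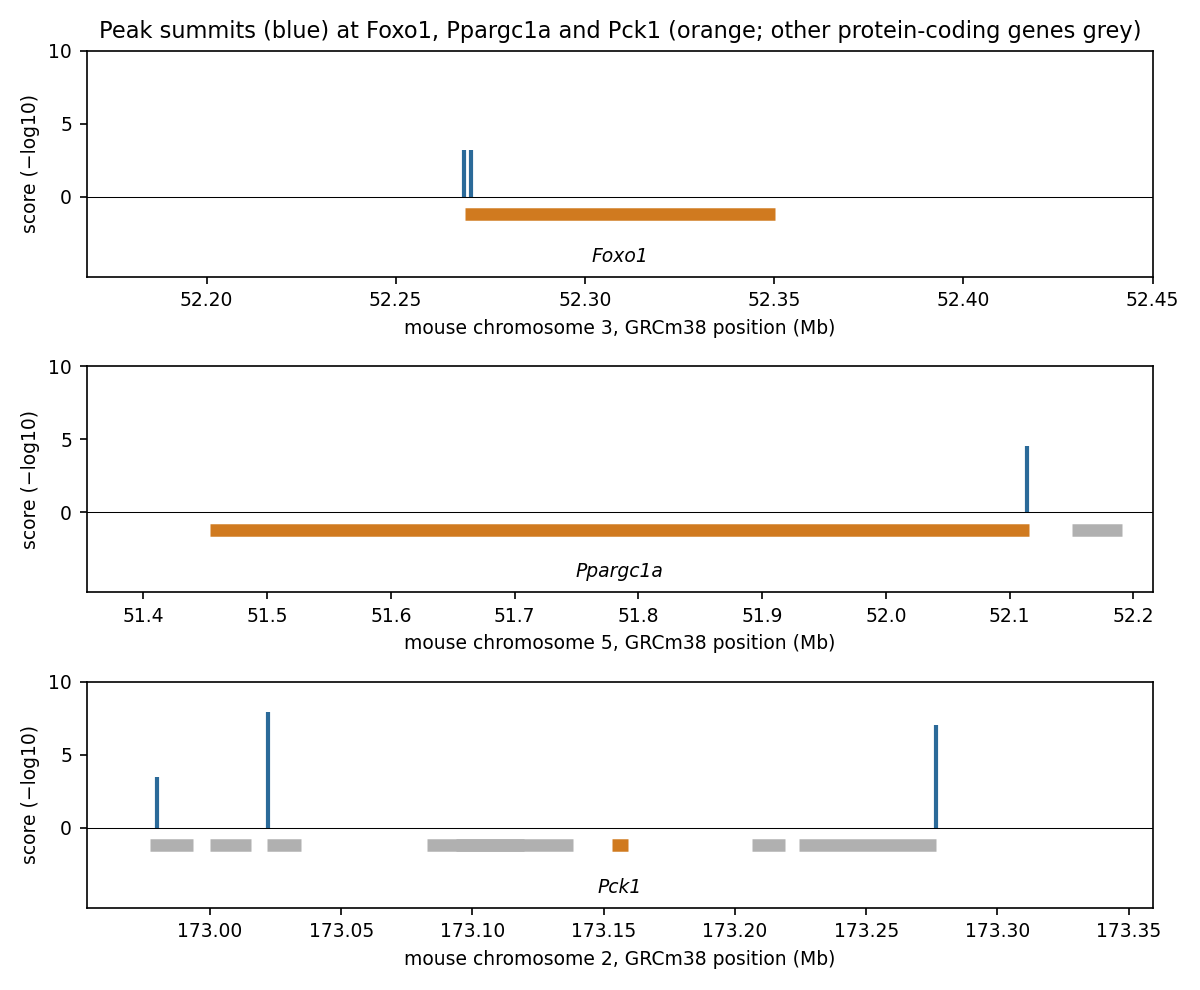
Peak summits (blue lines, height is the score as −log10 p or q) along the regions of Foxo1, Ppargc1a and Pck1 (orange bars; other protein-coding genes grey), by GRCm38 position in Mb. Foxo1 has 2 summits near its lower-coordinate end, each scoring 3.17. Ppargc1a has 1 summit scoring 4.54, which is 2190 bp inside its higher-coordinate end. No summit lies within 5 kb of Pck1.

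In total 2489 of 21900 protein-coding genes (11.4%, 95% interval 10.9 to 11.8) had a peak inside them or within 5 kb, against 1009.68 ± 26.1 (SD) for random placement. With 2 kb windows at gene ends alone, the count was 2058 genes, against 158 ± 13.2 for random placement. Among the 18 gene lists, FoxO, AMPK and mTOR signalling held the highest share of members with a peak, 10 of 23 (43.5%, 95% interval 23.2 to 65.5). Length-matched random lists held 3.54 ± 1.73 (SD), and 0.13% of them had 10 or more. With 2 kb windows at gene ends alone it was 7 of 23 (as many in 2.09% of random lists), and counting only genes whose own end was nearest to the peak, a setting chosen after seeing the data, it was 8 of 23 (0.81%). It was the 1 list of 18 in the upper 5% of its random lists, where 0.513 lists would be there by chance. The members with the highest scores were Rictor (12.4), the defining subunit of mTOR complex 2, Mtor (7.89), the kinase of both mTOR complexes, and Foxo3 (6.04), a relative of Foxo1. Ppargc1a (4.54), Crtc2 (4.22), a coactivator of CREB, and Prkag2 (3.76), a regulatory subunit of AMPK, followed. The Rictor, Mtor and Prkag2 summits lay 113, 120 and 879 bp from a gene end, and that of Crtc2 was nearer to an end of Dennd4b. The list was written with Foxo1 and Ppargc1a in mind and is not independent of what is known of the study, so it was also counted without them, again after seeing the data: 8 of 21 members had a peak, and 0.88% of random lists had as many. In the 50% of peaks with the highest scores the list no longer stood apart, with 3 of 23 members (13.04%) and as many in 28.2% of random lists.

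The metabolic lists did not stand apart from random lists. Fatty acid oxidation and mitochondrial biogenesis had peaks at 5 of 19 genes (26.3%; as many in 11.7% of random lists). Besides Ppargc1a these were Ppara (6.78), a nuclear receptor for fatty acids, Tfam (3.17), the mitochondrial transcription factor, Hadha (2.77), a subunit of the trifunctional β-oxidation enzyme, and Acadl (2.08), a long-chain acyl-CoA dehydrogenase; the Hadha summit was nearer to an end of Garem2. With 10 kb flanks the list had 7 of 19 members with a peak, and 1.89% of random lists had as many. Pentose phosphate and glutathione genes had 3 of 14 (as many in 23.6%): Txnrd1 (9.18), a thioredoxin reductase whose summit was nearest to an end of Eid3, Tkt (6.01), the transketolase, and Rpia (2.51), an isomerase of the same pathway. Glycolysis had 3 of 16 (32.2%): Pkm (7.89), which encodes pyruvate kinase, Pgam1 (4.54), a phosphoglycerate mutase, and Ldha (2.12), a lactate dehydrogenase subunit. Gluconeogenesis and glycogen metabolism had 3 of 20 (53.4%), among them Ugp2 (6.595), which makes UDP-glucose, and G6pc3 (10.5), a glucose phosphatase whose summit, 4407 bp away, was nearer to Lsm12. Ketone body metabolism and transport had 0 of 10, which allows a share of up to 30.0% by 3 counts of the total (exact upper limit 30.8%).

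T cell lists were close to their random lists or without a peak. Memory and naive-state genes had 3 of 24 (12.5%; as many in 60.8% of random lists): Foxo3, Foxo1 and Eomes (3.17), a T-box factor of memory and effector cells. T cell receptor signalling and identity had 4 of 26 (52.7%): Ets1 (7.996) and Nfatc2 (7.95), transcription factors with summits 59944 and 30360 bp inside the gene, Bcl11b (7.89), a factor of T cell commitment, and Plcg1 (4.09), a phospholipase of receptor signalling. Inhibitory receptors and exhaustion had 3 of 16 (33.9%): Nr4a3 (11.6), a receptor-induced nuclear receptor, Lag3 (5.04), an inhibitory receptor whose summit was nearer to an end of Ptms, and Eomes. Lysine acylation writers and erasers had 3 of 22 (63.4%): Crebbp (6.83), an acetyltransferase, Hdac2 (4.09), a deacetylase, and Sirt1 (2.49), an NAD-dependent deacylase. Effector and cytotoxic genes had 0 of 24, which allows a share of up to 12.5% by 3 counts of the total (exact upper limit 14.2%), and 7.59% of random lists also had none. Common-gamma-chain cytokine signalling had 0 of 17, as did 10.1% of random lists.

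The listed markers of other blood cells found in spleen had no peak: 0 of 12 for B cells, 0 of 15 for myeloid cells, 0 of 11 for CD4 helper and regulatory T cells and 0 of 10 for NK cells. This holds for the chosen list members and not for every gene that these cells express. Whether the profiled CD8+ cells express some of these genes too was not examined, so the counts do not set the cell types apart. For each list alone, 23.6%, 24.8%, 31.4% and 32.8% of random lists also had none; joined after these counts were seen, they had 0 of 48, as did 0.64% of random lists. The ubiquitously expressed genes had 1 of 24 (Actb, encoding β-actin, 8.52; as many in 88.4% of random lists), and the neuronal genes had 1 of 20 (as many in 97.3%). Large receptor families that T cells do not use were nearly free of peaks. Of 1110 olfactory receptor genes 1 had a peak (0.0901%, 95% interval 0.00228 to 0.501), against 31.2 ± 4.64 (SD) in random lists, and of 355 vomeronasal receptor genes none (0) had a peak, against 22.3 ± 4.37. The interval and the random lists treat genes as independent. Family members that lie next to each other may not be, so the spread may be wider.

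**Figure D3:**
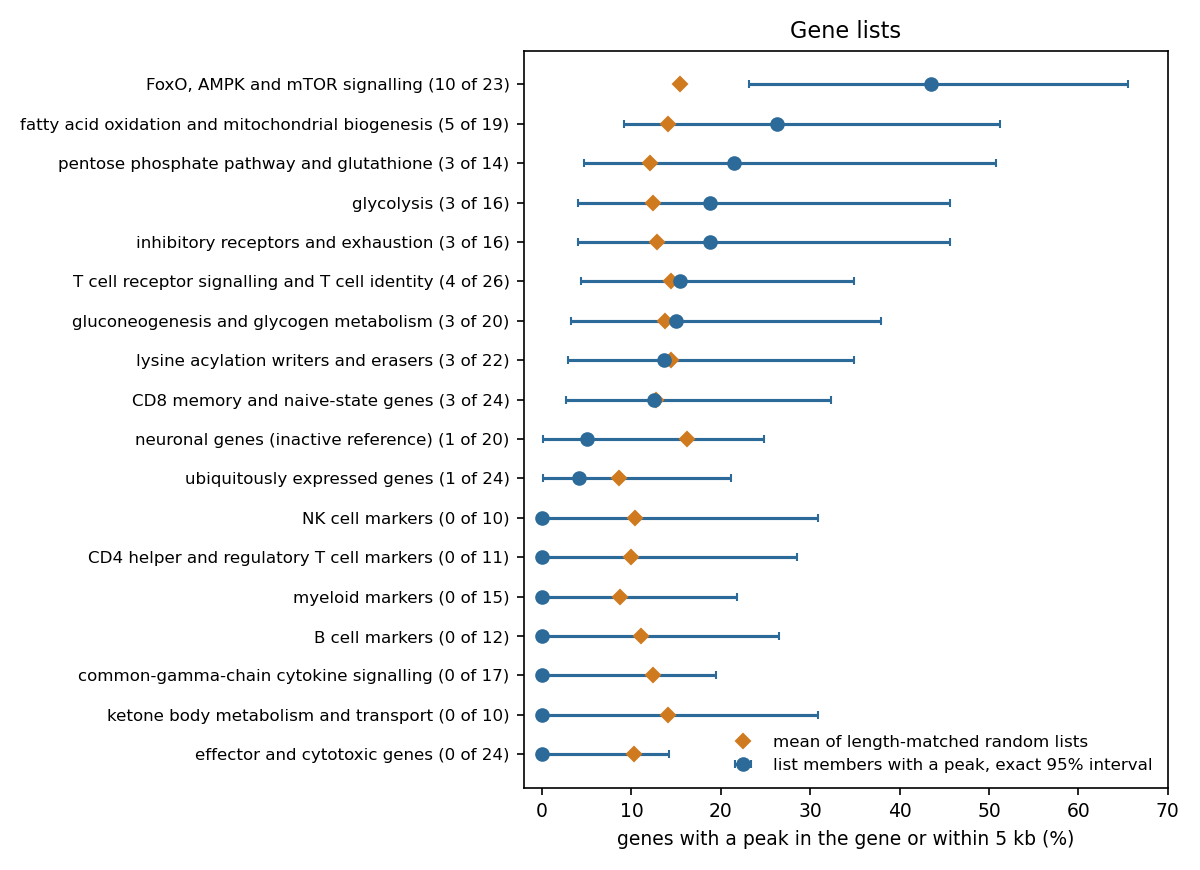
Share of genes with a peak inside them or within 5 kb (%, horizontal axis) in each of the 18 gene lists, with exact 95% binomial intervals (blue) and the mean of 10000 length-matched random lists (orange diamonds). The interval of FoxO, AMPK and mTOR signalling, 23.2 to 65.5%, is the one that lies above its random mean; 7 lists have no member with a peak.

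The highest scores were not at nuclear gene ends. Of the 20 peaks with the highest scores, which are also the 20 peaks that scored over 20, 8 were on the mitochondrial genome and 2 were within 2 kb of a nuclear gene end. The top score, 1167.46, was on chromosome 2 at 98667138, 1035.5 kb from the nearest protein-coding gene, Lrrc4c. Scores of 243 and 173 followed on chromosome 17 at 39844301 and 39848522, the latter inside the long non-coding RNA AY036118, and beside the annotated ribosomal RNA pseudogene Rn18s-rs5. The mitochondrial summits with the highest scores were in COX1 (165), CYTB (63.2) and ND1 (60.5 and 42.4), followed by 2 in mt-Rnr2 (34.5 and 32.5), ND4 (33.5) and ND2 (30.4). Others were inside Zc3h7a on chromosome 16 at 11144117 (131), on chromosome 9 at 3000485 (114), inside Filip1l and Cmss1 on chromosome 16 at 57391550 (96.7), inside Sfi1 on chromosome 11 at 3193433 (58.0), inside Cdk8 on chromosome 5 at 146261113 (50.5), and on chromosome 15 at 75086803 (34.4). Stambpl1 on chromosome 19 (20.9) had a summit 2162 bp inside. The 2 at gene ends were Psap on chromosome 10 (43.4), which encodes the lysosomal protein prosaposin, with a summit 169 bp inside the gene, and Agap2, also on chromosome 10 (25.5), 324 bp inside.

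Peaks with lower scores lay mostly at gene ends. Of the next 20 peaks by score, 15 were within 2 kb of a gene end and 5 were farther, those nearest to Clcn4, Mid1, Gramd1a, 9530057J20Rik and Trim24. Among the 15, chosen after their values were seen, were Rbm6 (19.5), an RNA-binding protein, Kdm4b (17.8), a histone lysine demethylase, Tspan2 (17.8), a tetraspanin, Vdac1 (17.1), the outer-membrane channel of mitochondria, Copb1 (16.3), a coatomer subunit, Snx8 (16.2), a sorting nexin, and Cs (14.7), the citrate synthase. Their summits lay 904, 254, 157, 167, 204, 20 and 346 bp from a gene end. Of the nuclear peaks that scored up to 20, 1807 of 2183 (82.8%, 95% interval 81.1 to 84.3) were within 2 kb of a gene end, against 2 of 12 (16.7%, 2.09 to 48.4) of those over 20.

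Few genes had several peaks. Counted inside genes or within 5 kb, COX1, ND1 and ND2 of the mitochondrial genome had 7 peaks each, ATP6, ATP8 and COX2 had 5, COX3, ND4 and ND4L had 3 and the other 4 had 2. The annotated mitochondrial span is 0.0154 Mb, so with these flanks the same 9 peaks were counted for several genes. No peak had its highest-scoring summit inside ATP6, ATP8 or COX2. Of the nuclear genes, 2366 had 1 peak, 103 had 2 and 7 had 3. The 7 were Foxl2, a forkhead factor, Nsd1, a histone lysine methyltransferase, Ptch1, the hedgehog receptor, Gse1, Lrrc8d, a subunit of volume-regulated anion channels, Zfp978 and the predicted gene Gm46725. OT-I cells carry a rearranged T cell receptor transgene. The 7 T cell receptor and immunoglobulin loci held 0 peaks, against 4.19 at uniform random placement for the immunoglobulin loci and 1.53 for the T cell receptor loci, and 0 of 665 annotated segments had a summit within 1 kb. Uniform placement may overstate what these loci would hold, because peaks were concentrated at ends of protein-coding genes. Away from those ends they were 0.344-fold (inside genes) and 0.0838-fold (outside genes) of random placement. The counts therefore do not show that the loci were depleted.

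Autosomes differed moderately in peak density and the X chromosome held few peaks. The 19 autosomes carried between 0.546 peaks per Mb (chromosome 14) and 1.39 peaks per Mb (chromosome 11), while X carried 22 peaks, 0.129 per Mb (95% Poisson interval 0.0808 to 0.195), 6.90-fold below the autosomal mean of 0.889. Over the genome mean this was 0.159, and 0.0869 in the top 50% of peaks. Counted by genes, 14 of 966 X genes (1.45%, 95% interval 0.795 to 2.42) had a peak within 2 kb of an end, against 9.82% (9.42 to 10.2) of autosomal genes. The lowest autosome was chromosome 7 (5.57%), and the highest was chromosome 12 (12.96%). X genes with a summit nearby included Tab3 (6.78), an adaptor of TAK1 signalling, Tsc22d3 (5.63), a glucocorticoid-induced factor, and Suv39h1 (2.51), an H3K9 methyltransferase, all chosen after their values were seen. The Y chromosome had 2 peaks, at 90744458 and 90807488, which were not used to tell the sex of the cells.

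**Figure D4:**
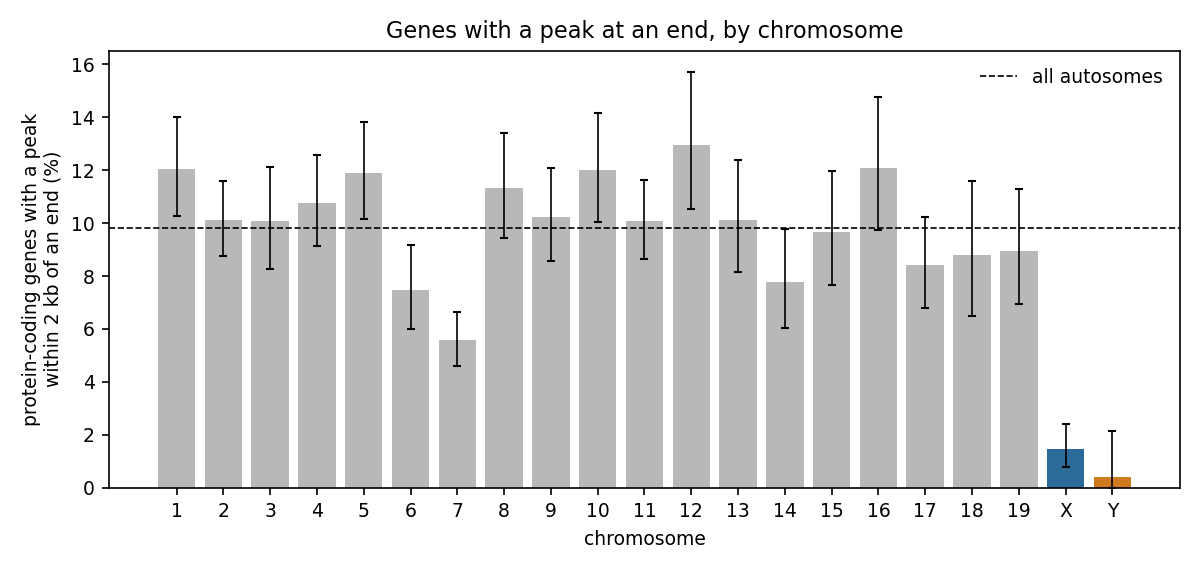
Share of protein-coding genes with a peak within 2 kb of either end (%, vertical axis) by chromosome, with exact 95% binomial intervals; the dashed line is the share over all autosomes, 9.82%. The X chromosome, at 1.45%, lies below every autosome, of which chromosome 7 is the lowest at 5.57%.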

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

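The test in this part was chosen after the result was seen. The mitochondrial genome, which carries no histones and lies outside the nuclear chromatin that the antibody addresses, held 9 peaks with 17 summits. These peaks, over an annotated span of 0.0154 Mb, were 719-fold as dense as the nuclear mean. A candidate explanation for these and for the other highest scores is sequence present in many copies per cell, such as mitochondrial DNA, ribosomal DNA (Rn18s-rs5 lies beside the chromosome 17 peaks) and satellite repeats. Of the nuclear peaks scoring over 20, 16.7% lay within 2 kb of a gene end, against 82.8% of those scoring up to 20. This is the observation that prompted the explanation and does not bear on it. No biological explanation was tested, and without genome sequence or the input's own signal the copy number at each place stays open.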

How the results depend on the processing

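Peaks lay at gene ends above random placement under each alternative that was set against such placement. The share of peaks near gene ends was 78.6% in the 10% of peaks with the highest scores, 75.6% with a 1 kb window, 87.6% with a 5 kb window and 87.5% with all annotated genes. The fold over random placement was 14.9 when placed over the whole genome, 12.4 and 8.12 in the top 50% and top 10% of peaks, 21.2 and 6.56 with 1 kb and 5 kb windows, 7.29 with all annotated genes, 13.7 without mitochondrial peaks and 13.8 without peaks scoring over 20; a wider window or more genes raises the random share by construction. The top 50% of peaks gave 1262 genes with a peak, since fewer peaks were used. Lists in the upper 5% of random lists numbered 2 with 10 kb flanks and 0 in the top 50% of peaks; lists in the lower 5%, 0 in the main count, numbered 1 with 10 kb flanks (effector genes, 4.77%) and 1 when only the gene with the nearest end was counted (neuronal genes, 0 of 20). In the top 50% of peaks, 28.2% of random lists matched the FoxO, AMPK and mTOR list (13.04% of members with a peak), fatty acid oxidation had 5.26% and neuronal genes 0%; fewer peaks were used there, and the cause was not tested further. X peaks per Mb over the genome mean were 0.0869 in the top 50%, against 0.159. This X setting and those without mitochondrial peaks, without peaks over 20, with all summits, with named genes alone, with nearest ends alone and with the FoxO, AMPK and mTOR list less Foxo1 and Ppargc1a were chosen after seeing the data. Matching on repeats or GC, leaving out repeats, an overlap of 50% of a peak, any overlap of whole peaks and peak width were not run. No paired analysis was possible because 1 ChIP library was profiled. A single library and coarse scores limit what the list can show: a gene without a peak was not called at this depth, which does not show that the mark is absent.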

Other observations

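All tests in this part were chosen after the results were seen. Genes grouped by the start of their symbol (109 groups with at least 20 named genes) were set against random lists. Genes starting with Zbtb, most of which encode BTB-domain zinc finger transcription factors, had a peak in 16 of 41 cases (39.0%, 95% interval 24.2 to 55.5), against 5.11 ± 2.103 (SD) in length-matched lists. Examples, chosen after their values were seen, were Zbtb4 (6.63), Zbtb48 (6.08), Zbtb7a (5.12) and Zbtb24 (4.26), with summits 242, 183, 1149 and 171 bp from a gene end. Spermatogenesis-associated Spata genes (9 of 30; as many in 0.42% of random lists), protein phosphatase Ppp genes (18 of 77; 1.17%) and centrosomal Cep genes (12 of 38; 1.51%) were also in the upper 5%, but in 4 of the 9 Spata genes, 3 of the 18 Ppp genes and 1 of the 12 Cep genes the summit was nearest to an end of another gene. Cytochrome P450 Cyp genes (2 of 99; as few in 0% of random lists), interleukin and interleukin receptor Il genes (1 of 83, Il10rb; 0.01%) and cell-surface Cd genes (3 of 100, namely Cd37, Cd47 and Cd80, whose summit was nearer to an end of Adprh; 0.14%) were low. In all, 5 groups were in the upper 5%, where 3.59 would be expected by chance from their random lists, and 13 were in the lower 5%, where 2.57 would be. These expectations treat genes as independent, which members of a group that lie next to each other may not be.

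Lists were also joined after each was seen to hold no peak, so that a low share was part of the choice. The 4 lists of other blood cells had 0 of 48 genes with a peak (as few in 0.64% of random lists), and the effector and common-gamma-chain lists had 0 of 40 (1.11%). In the top 50% of peaks these were 9.95% and 10.35%. Over all 18 lists together, 34 of 313 genes had a peak, against 39.5 ± 5.84 (SD). Peaks at gene ends were also scarcer at short genes: 1.69% of genes in the shortest of 10 length bins (median 942 bp) had one, against 15.7% in the ninth bin (median 76506 bp) and 12.97% in the tenth (median 184828 bp), but the windows at both ends overlap in the shortest genes and cover less sequence there. Among named genes alone these were 2.50%, 16.1% and 13.1%.

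The Zbtb excess was 5.18 SD of its random lists, and when peaks were shuffled among genes of like length, any of the 109 groups reached as much in 0.14% of 10000 shuffles, which argues against gene length with the choice of 1 group among many. Peaks that belong to neighbouring genes are the other explanation tested: counting only genes that own the end nearest to a summit within 2 kb left 14 Zbtb genes, and 0.01% of random lists had as many. The 16 summits were distinct and lay on 12 chromosomes, so a single cluster does not carry the count. In the top 50% of peaks the share was 21.95%. Base composition was not tested, no biological explanation was tested, and the excess stays a hypothesis.

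The X chromosome held few peaks, and the number and length of its genes do not account for it as the whole cause. Of 802 named X genes, 1.75% (95% interval 0.958 to 2.91) had a peak at an end, against 10.2% of named autosomal genes of the same lengths. The genes were matched on length alone, so the kind of genes that X carries was not tested and stays open. A second explanation is 1 copy of the X chromosome per cell, as in male cells, which would lower the reads and so the scores on X. The median score of the 22 X peaks was 3.76, against 5.04 on autosomes, and 2.88% of random sets of autosomal peaks had a median as low. In the top 50% of peaks the X density over the genome mean was 0.0869, against 0.159 with all. That density restates the lower scores on X and adds no separate support. If 1 copy halved each score, 67.2% of autosomal peaks would still reach the lowest score in the list, 1.49-fold fewer, against a density on X that was 6.90-fold lower (95% Poisson interval 4.56 to 11.01). How scores follow copy number is not known here, so that 1 copy stays open as part of the cause, the labels give no sex, no biological explanation was tested, and a lower level of the mark on X stays open.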
